A study of Homo sapiens with 4 samples.

How the data were processed

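Total RNA was extracted from THP-1 cells and hybridised as biotin-labelled cRNA to Affymetrix arrays, per the labels' protocols. The 4 arrays fall into 2 groups by their titles: control cells given buffer and cells given *Streptococcus suis*, with replicates 1 and 2 in each, all collected after 3 h. The design text counts 4 samples per condition on 4 arrays in total; how samples map to arrays is not given in the sources used here. A characteristic naming the bacterial strain is attached to control samples as well, and the titles were followed.

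The deposited table holds intensity values on a linear scale, made by the authors with MAS5 per the submitters' processing notes; its version, target intensity and detection calls are not given in the sources used here. The deposited intensities cover 54675 probe sets. After removing 2% of values at either end, the mean signals were 76.2, 71.8, 58.9 and 79.7 (control 1, control 2, infected 1, infected 2), so the arrays did not share a common trimmed mean. Since detection calls were not used here, fold differences of dim genes are uncertain.

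Probe sets were named through the GEO platform annotation, which can be old: 41097 have 1 gene symbol, 1801 have several and 11721 are unnamed here, and 62 are control probe sets. Of those with 1 symbol, 41043 were matched by gene identifier to the RefSeq gene table, used for names only, and 0 symbols changed. Values were log2 transformed, with the 4 zeros of the table set to 0.1; 0 zeros fell among the genes tested. Probe sets were kept if above the array's median on at least 2 of 4 arrays, control probe sets were left out, and the brightest probe set with 1 symbol stood for each gene, which gave 12260 genes from 22944 probe sets.

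Infected and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, two-sided, Benjamini-Hochberg adjusted p under 0.05), without further scaling between arrays. The prior degrees of freedom were infinite in this fit, so genes of like signal shared 1 variance, and 10.5 after centring. This design, 35 gene lists and the alternatives were fixed before the data were examined; since scaling altered the counts, centred and quantile-normalized values are given beside them. Lists with at least 3 tested genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. The genes named are the 15 highest and 10 lowest called genes with groups that do not overlap, up to 4 called members of each list or its 2 members with the smallest p, 20 inflammatory genes named in any case, and the control probe sets. Genes given with centred values, other than those, were chosen after their values were seen.

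The fit was tested on simulated data: 20 draws over 12260 genes with 200 changed genes each, the spread of the centred values and the brightness offsets of the real arrays. Of genes changed 1.5-fold, 2-fold and 3-fold, 0.97%, 30.7% and 75.2% were recovered without centring and 20.3%, 49.2% and 70.1% with it. False calls made up 29.4% of calls without centring and 5.50% with it. Simulated arrays with no offsets gave 5.45%, and the prior degrees of freedom were infinite in 20 of 20 draws without centring and 0 of 20 with it. In the list test, a shift of 0.5 in 20 genes was found in 20 of 20 draws, and 0 of 20 lists without a shift had an unadjusted p under 0.05.

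Alternatives were quantile normalization, median centring, adding 16 to each signal, raising signals to the 25th percentile, no filter, a filter at the 75th percentile, the mean of a gene's probe sets, a replicate block, leaving out each array, eBayes without a trend or robust, array weights, an adjusted p under 0.10 and a 1.5-fold size. Scaling by the trimmed mean, and centring together with the other choices, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.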

Results

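Messenger RNA levels were measured on Affymetrix arrays in THP-1 cells, a human line grown in suspension that was established from an acute monocytic leukaemia. Cells kept for 3 h with *Streptococcus suis* serotype 2, a Gram-positive pathogen of pigs that also infects people, were compared with cells given only buffer. The strain was SC19, at a ratio of 1 bacterium per cell. Each condition was represented by 2 arrays, labelled as biological replicates 1 and 2, and the number of arrays limits the precision of every value. The median signal was 15.6 and 14.4 on the control arrays and 12.6 and 16.5 on the infected arrays, so that the infected arrays differed more in overall brightness from each other than from the controls. Across the 12260 genes tested, log2 signals correlated at r = 0.954 between the control replicates, 0.955 between the infected replicates and 0.946 to 0.948 between arrays of different groups; these are correlations across genes, which are not independent replicates.

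To ask which genes responded to the bacteria, infected and control arrays were first compared gene by gene. On signals as deposited, 14 genes were higher and 1 gene was lower in infected cells (limma, Benjamini-Hochberg adjusted p under 0.05), and none of these 15 belongs to the immune and stress lists examined. The largest difference was in LOC101927166, an uncharacterised locus, whose signals of 19.6 and 21.1 in control cells compared with 143 and 134 in infected cells, a 6.80-fold difference (log2 2.77, 95% confidence interval 2.07 to 3.46, limma adjusted p = 5.5e-11). The control signals of LOC101927166 lay near the array medians, so the size of this fold is uncertain: with 16 added to every signal the log2 difference was 2.09, still past the threshold. ZC3H7B, a zinc finger protein gene, was higher by 1.78 on the log2 scale (interval 1.07 to 2.48), STAG3L3 by 1.60 (0.92 to 2.29) and ALMS1, the gene mutated in Alström syndrome, by 1.60 (0.94 to 2.26). STAG3L3 and ALMS1 stood at 0.92 and 0.99 without control replicate 1 and at 2.29 and 2.21 without control replicate 2, and neither passed the threshold without either array. DYNLL1, which encodes a dynein light chain, was the gene called lower: its signals were 5741 and 5351 in control cells and 3015 and 3618 in infected cells, a log2 difference of -0.75 (interval -1.08 to -0.42, limma adjusted p = 0.011).

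The other genes called higher included ERGIC1, at a 2.82-fold difference. On the log2 scale, the rest were NACA4P (1.73), CCDC152 (1.45), INO80D (1.41), ZCCHC7 (1.40), PECR (1.38), NLN (1.37), the kinase gene CDK13 (1.34), PGF, which encodes placental growth factor (1.33), and CMBL (1.30). In each of the 14 genes both infected arrays lay above both control arrays. NACA4P is annotated as a pseudogene, so its signal is uncertain because related transcripts can bind the same probes. Of the 14 probe sets, 9 carry the suffix by which Affymetrix marks probes that match several transcripts, 64.3% against 6.81% of all genes tested (Fisher's exact test, two-sided, p = 4.4e-08). For 9 of the 14 genes there were 24 further probe sets bright enough to be kept, and these had a median log2 difference of -0.15, against 1.40 for the probe sets tested. None of those 9 genes had a further probe set with at least 0.5 times the difference of the tested one. In ZC3H7B the further probe sets were lower, at -0.90 and -1.21.

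**Figure D1:**
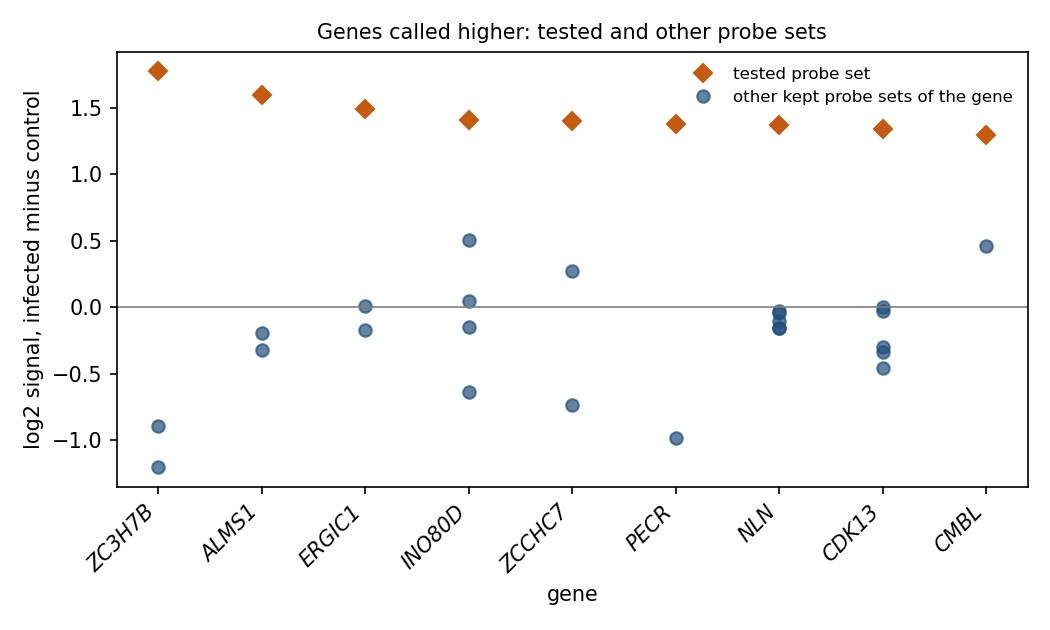
Log2 signal in infected minus control cells (vertical axis, mean of 2 arrays each) for the 9 genes called higher that have further kept probe sets. Diamonds are the probe sets tested and circles the 24 further probe sets of the same genes, whose median was -0.15.

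The number of genes called depended strongly on how arrays were scaled. With each array centred on its median, 256 genes were higher and 411 lower, and with quantile normalization 383 were higher and 259 lower. Higher genes thus made up 93.3% of calls as deposited, 38.4% after centring and 59.7% after quantile normalization, and the median log2 difference over all genes was -0.12, -0.07 and -0.03 in turn. All 15 genes called on deposited signals were also called after centring, in the same direction, and after quantile normalization. With eBayes without a trend on deposited signals, LOC101927166 alone of these 15 kept its call. That fit called 18 genes higher and 20 lower. At an unadjusted p under 0.05, 239 genes were higher and 379 lower as deposited, against 849 and 1681 after centring. For 206 genes called higher after centring, 532 further kept probe sets had a median of -0.01, against 0.66 for those tested. For 237 called lower, the medians were -0.16 and -0.50, and for genes not called the further probe sets had -0.10. A further probe set with at least 0.5 times the tested difference existed for 79 of the 206 and 135 of the 237. In simulated arrays with the brightness differences of these arrays, 29.4% of the genes called on uncentred values were false, against 5.50% after centring. The threshold thus did not hold the intended error rate on simulated uncentred signals. The simulated spread was drawn from the centred fit, with genes independent, so 5.50% does not measure the error rate of the centred calls.

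Single arrays also moved the counts. Without control replicate 1 the fit on deposited signals called 1 gene higher and 0 lower, and without control replicate 2 it called 2 higher and 0 lower. Without infected replicate 1 the counts were 121 and 8, and without infected replicate 2, the brighter array, they were 91 and 2519. After centring, the corresponding counts were 66 and 20, 72 and 20, 211 and 404, and 263 and 624. Centred values fitted with a single prior variance, without a trend on signal, gave 0 genes in either direction (limma, lowest adjusted p = 0.097; in that fit 686 genes were higher and 989 lower at an unadjusted p under 0.05).

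By size alone, 220 genes were at least 2-fold higher and 255 at least 2-fold lower in infected cells with arrays that did not overlap. These counts were 254 and 230 after centring. Of all genes tested, 34.1% had groups that did not overlap as deposited (10.1% higher and 24.0% lower), where chance gives 33.3%, or 16.7% per direction. This share was 50.3% after centring (19.0% higher and 31.3% lower) and 50.6% after quantile normalization (22.8% and 27.8%). Most of the 2-fold differences were in dim genes: adding 16 to every signal left 34 higher and 16 lower. With 2 arrays against 2 no permutation of the labels can give a two-sided p under 0.333. The p-values as deposited rest on a spread pooled over genes of like signal, not on each gene's own spread. NACA4P, with signals of 3193 and 6599 in infected cells, thus had limma adjusted p = 2.1e-13. After centring, a gene's own spread counted in part.

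To see whether the bacteria raised the inflammatory genes by which monocytes usually answer a Gram-positive pathogen, 20 genes chosen before the data were examined were read out one by one. Of the 16 that could be tested, 0 passed the adjusted threshold as deposited and 0 passed when adjusted over the list alone (limma; 2 had an unadjusted p under 0.05). TNF, the central inflammatory cytokine, had signals of 358 and 328 in control cells and 172 and 248 in infected cells, so that both infected arrays were lower (log2 difference -0.73, interval -1.39 to -0.08, limma adjusted p = 0.97). After centring, TNF was the 1 gene of the 16 past the threshold (-0.68, interval -0.93 to -0.42, limma adjusted p = 0.0078). Without infected replicate 1 the difference of TNF as deposited was -0.47, and without infected replicate 2 it was -0.996, the latter past the threshold. The adjusted p of TNF ranged from 0.0038 to 1 over the alternatives.

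CXCL8, the neutrophil chemokine interleukin-8, differed by -0.03 (interval -0.62 to 0.56), IL1B by -0.24 (-0.90 to 0.42) and CCL2 by -0.42 (-1.08 to 0.23). CCL4 differed by -0.86 (-1.68 to -0.04, limma adjusted p = 0.97). The NF-kappaB feedback genes NFKBIA and TNFAIP3 differed by -0.05 (-0.52 to 0.42) and 0.00 (-0.55 to 0.55), and the intervals of these probe sets leave out a 2-fold rise. The values for ICAM1, PTGS2, SOD2, TLR2, CD14, IL1RN, F3 and HMOX1 were -0.08, -0.58, 0.37, -0.21, -0.11, -0.01, -0.49 and -0.02. Genes near 0 changed sign with scaling: after centring and quantile normalization CXCL8 was at 0.03 and 0.12, NFKBIA at 0.0041 and 0.13, IL1RN at 0.05 and 0.09, and HMOX1 at 0.04 and 0.15. CD14 turned to 0.0066 with quantile normalization and 0.0062 with trimmed-mean scaling, which was chosen after seeing the data and also turned ICAM1 to 0.03. IL10, an anti-inflammatory cytokine, had dim signals of 3.7 and 7.3 in control cells and 19.4 and 21.4 in infected cells (log2 1.97, interval -0.31 to 4.26, limma adjusted p = 0.98), and its difference was 0.76 with 16 added to every signal. Further kept probe sets of these genes had values of -0.57 for CXCL8, -0.51 for IL1B, -0.44 and -0.92 for IL1RN, 0.37 and -0.55 for ICAM1, 0.30 for TNFAIP3 and -2.55 for NFKBIA, the last from a dim probe set with signals of 33.4 and 17.8 in control and 1 and 17.4 in infected cells. IL6, CCL20 and IL12B were too dim to be tested, and the probe set for CCL3 names 3 genes.

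**Figure D2:**
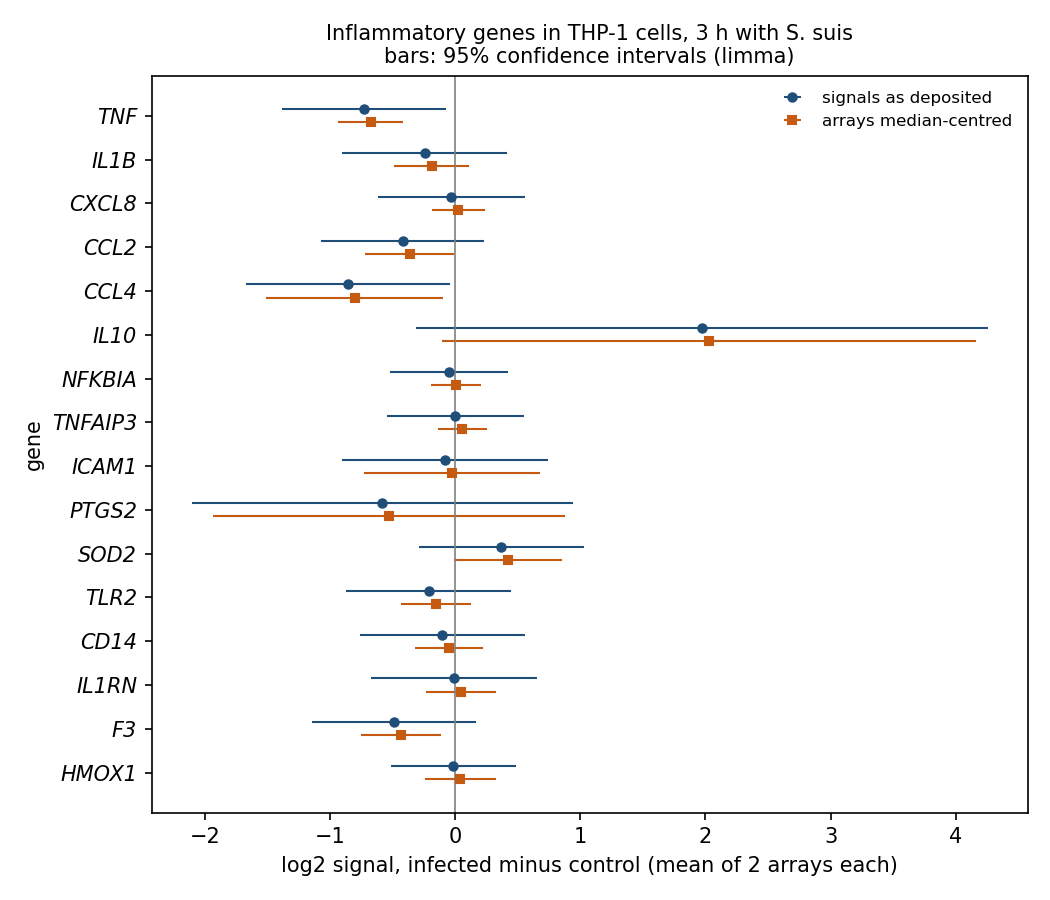
Log2 signal in infected minus control cells (horizontal axis) for 16 inflammatory genes, with 95% confidence intervals from limma, for signals as deposited (circles) and after median centring (squares). TNF lies at -0.73 and -0.68, CXCL8 at -0.03 and 0.03, and the wide interval of IL10 belongs to a dim probe set.

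Gene groups were then tested as a whole. As deposited, 5 of 33 lists passed the threshold, all lower in infected cells: metallothioneins (8 genes, median log2 -0.42, camera adjusted p = 0.018), housekeeping genes (24 genes, -0.25, 0.035), oxidative phosphorylation (21 genes, -0.21, 0.045), the G2 and M phases of the cell cycle (29 genes, -0.28, 0.047) and ribosomal proteins (20 genes, -0.13, 0.047). The median over all genes tested was -0.12, so that of the ribosomal proteins hardly differed from it. None of the 5 lists passed with an estimated correlation between genes, each at camera adjusted p = 0.9997. That test has 2 residual degrees of freedom and little power, so not passing does not show that the lists were unchanged. The estimated correlations were 0.79, 0.68, 0.92, 0.91 and 0.69 in the order given, above the preset 0.01 on which the calls rest. With fry the lowest adjusted p over the 33 lists was 0.93. The medians of the 5 lists moved with single arrays. In the order given they were -0.27, -0.08, -0.01, -0.04 and -0.05 without infected replicate 1, and -0.60, -0.40, -0.41, -0.51 and -0.16 without infected replicate 2. Each of the 5 lists lost its call when either control array was left out, housekeeping, oxidative phosphorylation and G2 and M phase genes also without infected replicate 1, and ribosomal proteins without infected replicate 2. Of the 581 list genes tested, 0 passed the gene-level threshold (limma, all genes tested); adjusted over the list alone, GADD45A, a DNA damage response gene (-0.98), and TUBB, a tubulin gene (-0.59), were lower, and APOC1, an apolipoprotein gene (1.08), was higher.

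After centring, 4 lists were lower: metallothioneins (camera adjusted p = 0.0025), oxidative phosphorylation and G2 and M phase genes (both 0.0027), and oxidative stress genes controlled by NRF2 (0.038). Again none passed with an estimated correlation, the lowest camera adjusted p being 0.86. Estimated correlations were 0.31 for metallothioneins, 0.19 for G2 and M phase genes and 0.05 for NRF2 genes, above the preset 0.01. Their calls thus rest on a lower correlation than the one estimated. For oxidative phosphorylation the unadjusted camera p rose from 0.00023 to 0.056, although its estimated correlation (-0.02) lay under the preset 0.01. With 2 residual degrees of freedom the test with an estimated correlation has little power and does not decide against the 4 lists. Housekeeping genes and ribosomal proteins no longer passed, and the median of the ribosomal proteins turned to 0.03 after quantile normalization. In the centred fit 44 list genes passed over all genes tested. Among 8 metallothioneins, which bind zinc and copper, 4 were lower, MT1G by -0.67, MT1F by -0.46, and MT1E and MT1X by -0.44 each; their probes can be shared between members of this family. Among 29 G2 and M phase genes, 6 were lower, among them CENPA (-0.66), PLK1 (-0.54), TOP2A (-0.48) and CCNB1 (-0.38), and the kinase gene TTK was higher (0.50). The mean over all probe sets of TOP2A was 0.19, of the opposite sign. Among 19 NRF2 genes, CAT, which encodes catalase (-0.50), PGD and SQSTM1 were lower. Of the 19 differences, 13 were negative and 6 positive after centring. Adjusted over the list alone, 6 metallothioneins, 8 NRF2 genes and 12 G2 and M phase genes were lower after centring, and 2 G2 and M phase genes were higher.

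The remaining immune lists did not pass. Of 12 chemokines tested, 12 had negative differences as deposited (median -0.27, camera adjusted p = 0.52), and after centring 9 did. For 15 inflammatory cytokines the median was -0.03 and the mean 0.13 (camera adjusted p = 0.93). For 29 interferon response genes the median was -0.21 (0.82), with OAS1 at -0.88 and OAS2 at -0.76. In the centred fit, NFKB1 (-0.40), TREM1, an amplifier of inflammation in myeloid cells (-0.57), NEK7, a component of the NLRP3 inflammasome (-0.55), and MYC (-0.43) were lower, and JUND was higher (0.56). With quantile normalization NFKB1 did not pass (-0.32, limma adjusted p = 0.093), while TREM1, NEK7 and JUND did. Genes that mark monocytes had a median of -0.29 (22 genes, camera adjusted p = 0.12), and LAPTM5 and CTSG were lower after centring. Markers of other cell types were few and dim: 5 B cell genes, 3 NK cell genes, 4 epithelial genes and 7 fibroblast genes had medians of -0.35, -0.64, 0.35 and 0.14, with 0 calls (limma; 1 epithelial gene, KRT7, had an unadjusted p under 0.05). After centring, the 4 epithelial genes passed as a set with fry, in the higher direction (adjusted p = 0.038), but not with camera (0.67), while KRT7 was lower when adjusted over the list alone. KRT18, an epithelial gene with signals of 4.9 and 5.2 in control and 23.2 and 19.6 in infected cells, passed the filter only through the infected arrays. Its higher value was thus in part fixed by the filter. The T cell and erythroid lists had 2 tested genes each and were not tested as sets.

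Control probe sets gave values beside these groups. In control 1, control 2, infected 1 and infected 2, GAPDH ratios of 3' to 5' end signal were 1.28, 1.22, 1.51 and 1.27. For ACTB the ratios were 1.13, 1.17, 1.53 and 1.44 in the same order. The ACTB ratio was thus higher on both infected arrays than on both control arrays, while the GAPDH ratios of the groups overlapped. The hybridisation controls bioB, bioC, bioD and cre differed on average by 0.19, 0.19, 0.20 and 0.23 on the log2 scale, with overlapping arrays for bioB and bioC, and the poly(A) controls lys, phe, thr and dap were higher on both infected arrays by 0.72, 0.55, 0.60 and 0.71.

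**Figure D3:**
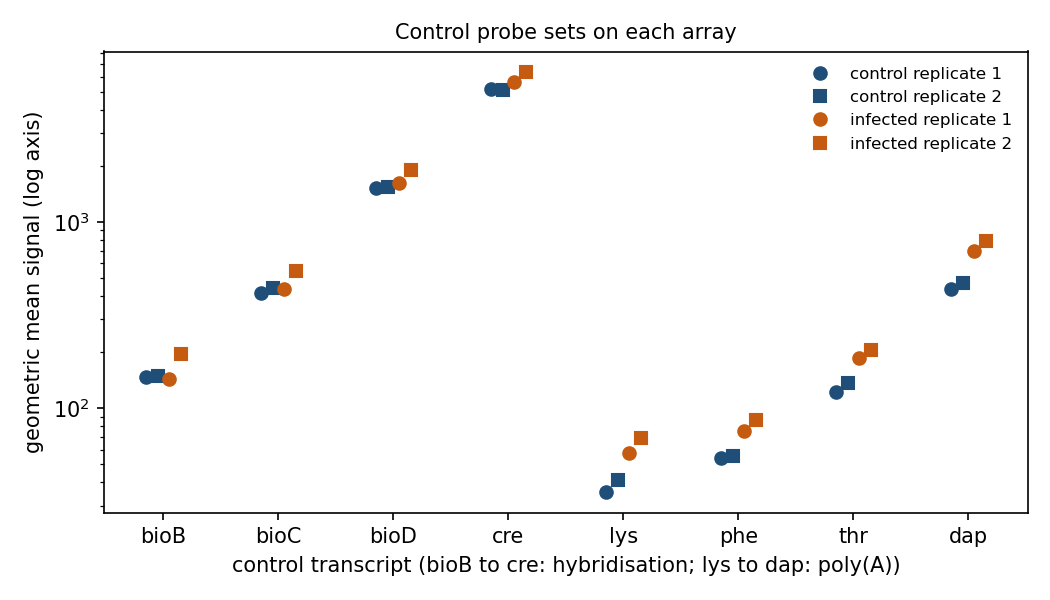
Geometric mean signal (vertical log axis) of the control transcripts on each of the 4 arrays, with control arrays in blue and infected arrays in orange. The poly(A) controls lys to dap were higher on both infected arrays, by 0.65 on the log2 scale over all 24 probe sets, against 0.20 for the 18 hybridisation probe sets.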

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

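All tests of explanations in this part were chosen after the results had been seen. Array controls and unnamed probe sets lie outside the gene comparison and were higher on both infected arrays than on both control arrays. Ribosomal RNA probe sets were among them, at 0.44 for 18S and 0.34 for 28S on the log2 scale, and so were the hybridisation controls bioD (0.20) and cre (0.23).

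The poly(A) controls, bacterial transcripts usually added to the RNA before labelling, were higher in infected samples by 0.72 for lys, 0.55 for phe, 0.60 for thr and 0.71 for dap. Brighter hybridisation or scanning does not account for all of this. The hybridisation controls together differed by 0.20 (pairwise range 0.04 to 0.36). The poly(A) controls together differed by at least 0.48 in every pair of an infected and a control array. The lowest pair of a single poly(A) control was 0.43, for phe. Less human messenger RNA relative to the added control may have produced the 0.65 difference of the poly(A) controls, and so may a larger amount of control. These cannot be told apart, because no amount of RNA or control was analysed here. An effect of infection on RNA content stays open and untested.

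Of the 4023 probe sets without a gene name that were bright enough to be kept, 134 were called higher and 2 lower in infected cells. This share was 3.33% higher (limma on signals as deposited). Low signal does not account for it, as 0.252% of named probe sets of matched signal were called higher. Probes that match several transcripts do not account for all of it, as unnamed probe sets without that mark reached 3.05%, against 0.206% of named ones. Overall brightness does not account for it either, as 11.1% were called higher after centring, against 1.54% of named ones at matched signal. Transcription that answers the infection stays open and untested, and the position of these probes in introns or between genes was not examined. The ACTB ratio of the control probe sets also differed between the groups. Such transcription therefore cannot be told apart from a difference between the RNA samples.

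The 14 genes called higher form the remaining pattern. A rise of the whole transcript is argued against for the 9 genes with further probe sets, whose median was -0.15. Median centring moved the differences of the 14 genes little, LOC101927166 from 2.77 to 2.82 and CMBL from 1.30 to 1.35. A uniform difference in brightness between the groups therefore does not make up their size. That 14 of the 14 stayed called adds little, since centring also lowered the median standard error from 0.34 to 0.19. Probes that match several transcripts may contribute, because 64.3% of the called probe sets carry that mark, but 5 do not. The 2 other ways to split the 4 arrays into pairs called 0 and 1 genes, against 15 for the real split, and such splits are too few for a share under 0.05.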

How the results depend on the processing

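Trimmed-mean scaling, and centring combined with other choices, were chosen after seeing the data. Counts are given as higher and lower, and the cause of each change was not tested except where fewer arrays or genes entered. Against 14 and 1 genes as deposited, quantile normalization gave 383 and 259, median-centred arrays 256 and 411, trimmed-mean scaling 324 and 236, and the mean of the probe sets of a gene 7 and 11. Lower genes numbered 0 with no filter, 20 with eBayes without a trend and 4 at an adjusted p under 0.10. Leaving out 1 array gave 1 to 121 and 0 to 2519; the lone array is then assumed to vary like the other group.

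Against 220 and 255 genes of at least 2-fold, a 1.5-fold size gave 520 and 826, log2(signal + 16) 34 and 16, no filter 1070 and 1293, and the 75th percentile filter 42 and 10. Leaving out 1 array gave 217 to 512 and 286 to 759.

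Against 5 lists past the threshold, camera with an estimated correlation gave 0, fry 0, quantile normalization 1, signals raised to the 25th percentile 3, no filter 2, the 75th percentile filter 1, the mean of probe sets 0 and trimmed-mean scaling 3. Leaving out 1 array gave 0 to 5.

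Deviations of same-numbered arrays from their group means correlated at 0.0049 over genes, so no shared deviation was seen. This single value cannot settle whether the replicate numbers pair the samples. The replicate block gave 3 and 0 genes and 0 lists as deposited, left the 2-fold counts at 220 and 255, and gave 545 and 1066 genes after centring.

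After centring, against 256 and 411, the mean of probe sets gave 27 and 51, eBayes without a trend 0 and 0, an adjusted p under 0.10 gave 396 and 743, and no filter left 259 lower. Leaving out 1 array gave 66 to 263 and 20 to 624. Against 4 centred lists, an estimated correlation gave 0, fry 1 (the epithelial markers, not among those 4), and leaving out 1 array 2 to 7.

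The median of the ribosomal proteins turned to 0.033 with quantile normalization. The camera direction of oxidative phosphorylation turned with the mean of probe sets, at a median of -0.18. ZC3H7B turned to -0.11 with the mean of its probe sets. Of the 15 called genes, LOC101927166 kept its call under all 15 alternatives. Signal over background limits dim genes.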

Other observations

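The test of noncoding genes below was chosen after the data had been seen. Of 15 regulators of messenger RNA decay and processing, 2 were called higher and 1 lower after centring, and the list did not pass (median -0.02, camera adjusted p = 0.67). DICER1, which cuts microRNA precursors, had signals of 316 and 302 in control cells and 474 and 519 in infected cells (log2 0.74 after centring, 0.68 as deposited), KHSRP was higher as well (0.42 after centring), and ZFP36, which promotes the decay of cytokine messengers, was lower (-0.45). MALAT1, a nuclear noncoding RNA, had signals of 486 and 339 in control cells and 655 and 790 in infected cells (0.88 after centring, 0.83 as deposited). MALAT1 was chosen after its values were seen. None of these 4 genes passed as deposited.

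A hypothesis was that genes of noncoding transcripts were called higher more often than other genes. It was tested on the 455 genes whose symbols mark long intergenic, antisense, intronic, divergent or overlapping transcripts. MALAT1 and other noncoding genes without such a symbol are not in that set and count among the other genes. Of the set, 1.10% were called higher after centring against 2.13% of other genes, an odds ratio of 0.51 (95% interval 0.16 to 1.22, Fisher's exact test p = 0.18), so a higher share in this set was neither found nor excluded. Its genes were called lower in 0.44% against 3.46% (Fisher's exact test p = 4.6e-05). The median log2 differences after centring were -0.05 in the set and -0.07 in other genes. Signal was not matched between the set and other genes, so the lower share of calls does not by itself show a different response.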
